A study of Mus musculus with 12 samples.

How the data were processed

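Polyadenylated RNA of 6 mouse tissues was treated with bisulfite and sequenced, so that unmodified cytosines read as T and 5-methylcytosine (m5C) stays C. Per the labels, 12 libraries were made from wild-type C57BL/6 mice aged 8 to 10 weeks. There were 4 female libraries of muscle, 1 female and 1 male library each of lung, small intestine and spleen, and 1 female library each of heart and liver. Per the labels' protocols, polyadenylated RNA was taken with either of 2 kits, and bisulfite treatment used a modified commercial kit. Which library used which kit is not given in the sources used here. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt, Trimmomatic, HISAT2 2.10 and SAMtools were used and the genome build was mm10. What each tool did, how unconverted reads were filtered and how sites were chosen is not given in the sources used here.

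The deposited table lists 2498 cytosines, each with its chromosome, position, strand and gene. For each tissue it has 4 columns: per the file headers, these are the coverage (a count of reads), the m5C level (a fraction), a p-value and the authors' call of whether the position is an m5C site. The authors' deposited counts start at 10 reads, and the remaining cells are blank. A blank cell is called no coverage below, though it may stand for fewer than 10 reads. The authors' deposited fractions run from 0 to 1 and are given here as percentages. The authors' deposited p-values and their site calls, which are marked as other in unit, were used only to compare calls. Sites the authors called had at least 20 reads and a level of at least 10% in every tissue. Each tissue has 1 set of columns whatever its number of libraries, and how the libraries were combined is not given in the sources used here.

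Unconverted reads were recovered as the level times the coverage. In the 9926 filled cells this product lay within 0.000179 of a whole number. Coverage of at least 20 reads was required throughout. A site was counted as called in a tissue at a level of at least 10%. With 1 column set per tissue there is no spread between animals, so a planned replicate test on libraries could not be fitted, and the fallback fixed beforehand for pooled columns was used. Pairs of tissues, and each tissue against the other 5, were compared by the two-sided Fisher's exact test on unconverted and converted reads. All 6 tissues were compared by a chi-square test with p simulated from 10000 tables with fixed margins. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a site was called higher or lower at an adjusted p under 0.05 and a difference of at least 10 percentage points. For a tissue against the others, the difference was taken from the unweighted mean of the other 5 levels, and the test from their summed reads; the direction had to be the same in both, also when p was adjusted over a gene list alone. These tests compare the deposited columns and cover counting error only, not differences between animals. Whether reads are independent molecules is not given in the sources used here, and the 95% Wilson intervals of single levels also cover counting error only.

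Intervals of medians are 95% ranges over 2000 resamplings of genes, which describe the sites and not the animals. For each of 16 gene lists fixed before the data were examined, the median difference of a list was placed among 10000 random lists of the same size matched on mean level, with 1 site per gene and at least 3 genes. That percentile describes these columns, and no p-value was made from it, in place of the test planned for replicated data. Gene spans and biotypes came from RefSeq on GRCm38.p6, the assembly called mm10; 2440 of 2498 names matched and 2367 sites lay inside the span of their gene. Sites in protein-coding genes of 10 kb or more were divided by their distance to the ends of the gene, within 1 kb of the 5′ end, within 1 kb of the 3′ end, or elsewhere. Levels of 5′ sites and sites elsewhere were compared by a two-sided permutation test over genes with 100000 resamples.

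Named sites followed a rule fixed before the data were examined. They are the 20 sites with the smallest adjusted p over all tissues and a range of at least 10 points, the 5 highest and 5 lowest differences of each contrast and reported pair, the 10 highest mean levels, up to 4 most covered members of each list, and all sites in genes of the m5C machinery. In the first part 583 sites tied at the smallest p that the simulation can give, and ties went by chromosome, so that part names sites on chromosome 1 alone. The parts that need libraries on 1 side of a mean could not be applied.

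On simulated data, the pair test of 1097 sites covered in muscle and lung called 23.9%, 65.7% and 95.5% of sites with true differences of 10, 20 and 30 points, and 0.111% of unchanged sites. The 6-tissue test of 802 sites called 82.1%, 100% and 97.0%, and 0.498% of unchanged sites. In it the difference was placed in muscle alone, and fewer tables were simulated than in the main test. Muscle had a median of 627 reads at these sites, against 128 in lung and 99 in spleen. Its shares therefore do not describe differences that lie in lung or spleen. These shares describe simulated counts and cover counting error only. Spread between animals could not be measured from pooled columns, so the shares of unchanged sites are not error rates for differences between animals. Alternatives changed the coverage minimum, the level, the minimum difference, the summary of levels and the sites or tissues used. Female against male, agreement of replicates, models with spread between libraries and leaving out libraries were not possible with pooled columns. Sequence context, exons, untranslated regions and coding sequence were left out because no genome sequence or transcript model was used here. No unmodified control RNA was used here, so the rate of failed conversion was not measured. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.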

Results

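The table covered 2498 cytosines in 1964 genes, of which 2320 lay in protein-coding genes and 59 in lncRNA genes. Ryr1, the calcium release channel of skeletal muscle, had the most sites, 12. Sites with at least 20 reads numbered 1869 in heart, 1750 in muscle, 1556 in liver, 1609 in small intestine, 1184 in lung and 994 in spleen. Coverage summed over listed sites was 2910693 reads in heart, 4683960 in muscle, 2869803 in liver, 2117347 in small intestine, 261562 in lung and 304426 in spleen. The median coverage per site ran from 56 reads in spleen to 223 in muscle. A few transcripts took much of it: the Alb site in liver had 1177520 reads and the Myh4 site in muscle 1359239. Each tissue had 1 value per site, so no value below carries an error between animals.

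The first comparison asked how m5C levels differed between tissues at the same sites. At the 802 sites in 666 genes covered in all 6 tissues, the median level was 12.2% in muscle (95% range over genes 11.5 to 12.9) and 10.9% in heart (10.4 to 11.4). It was 5.11% in liver (4.37 to 5.76), 2.93% in small intestine (2.57 to 3.34), 1.78% in lung (1.42 to 2.09) and 1.31% in spleen (0.995 to 1.72). Summed reads over the same sites gave another order, 21.7% in heart, 19.5% in muscle, 9.28% in liver, 7.62% in spleen, 6.90% in lung and 5.75% in small intestine. Of these sites, 508 reached 10% in muscle and 452 in heart, against 230 in liver, 116 in small intestine, 92 in spleen and 88 in lung. The chi-square test over 6 tissues called 714 of 802 sites at an adjusted p under 0.05, and 611 of these also spanned at least 10 points. The highest level among those 611 lay in muscle at 333 sites, in heart at 173, in liver at 60, in small intestine at 21, in spleen at 14 and in lung at 10. A count chosen after the data were seen showed more heart and muscle sites just above the authors' 10% than just below it. At 100 reads or more, 170 muscle sites had levels from 10% to 12% and 75 from 8% to 10%, and heart had 182 and 109. Liver had 78 and 67. The other tissues went the other way, with 19 and 29 in lung, 48 and 65 in small intestine, and 9 and 15 in spleen. Of the listed sites, the authors called 980 in heart, 927 in muscle, 490 in liver, 297 in small intestine, 131 in lung and 96 in spleen. A site may be listed because its level was high in 1 tissue, so the medians and the counts at 10% depend in part on the listing.

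**Figure D1:**
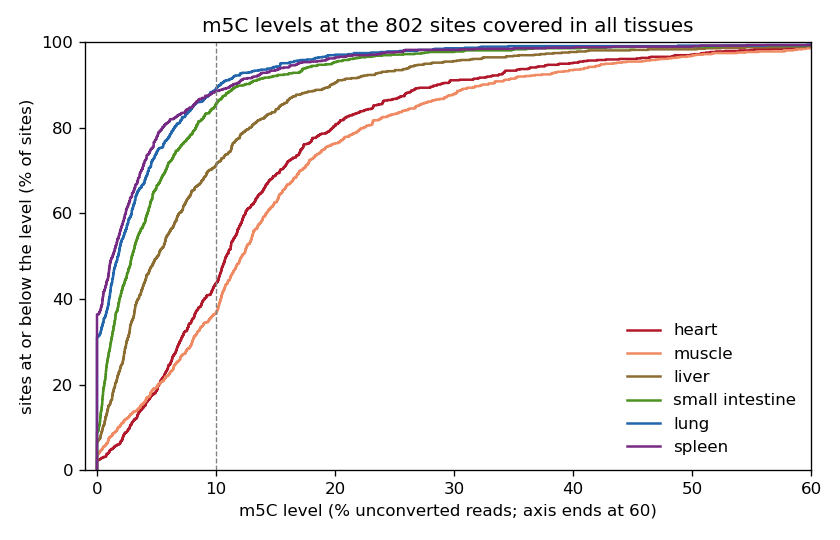
Cumulative share of the 802 sites covered in all tissues (vertical axis, percent of sites) at or below each m5C level (horizontal axis, percent), 1 line per tissue, with a dashed line at 10%. The lines of heart and muscle lie to the right of the others, with medians of 10.9% and 12.2%.

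Among sites named by the test over all tissues, Des, the gene of the muscle filament desmin on chromosome 1 at 75367402, had a level of 33.4% in muscle and 23.7% in heart, 17.2% in liver, 4.89% in lung, 0.528% in small intestine and 0% in spleen. Spleen had 0 unconverted reads of 293 there, and the 95% interval reaches 1.29%. Ndufa10, a subunit of respiratory complex I at 92469865, had 40.0% in heart, 37.4% in muscle, 15.3% in liver, 10.2% in small intestine, 8.96% in lung and 3.83% in spleen. Actr1b, a dynactin subunit, was at 32.2% in muscle and 12.5% in heart. Rnf149 went another way, with 20.2% in liver, 11.5% in muscle and 2.30% in heart. Map4k4, a kinase, had 14.4% in heart and 4.27% in muscle. Each of these had the smallest p that 10000 simulated tables can give, 1e-04.

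Each tissue was next set against the mean of the other 5. In muscle 273 sites were called higher and 4 lower, with a median difference of 7.39 points (6.47 to 8.09). Prkrir on chromosome 7 at 98717700 had 71.3% in muscle (68.7 to 73.9, 1169 reads) and a mean of 17.1% elsewhere. Akt2, a kinase of insulin signalling, had 61.1% against 11.5%, Aes, a transcriptional corepressor, 66.8% against 17.2%, Atn1 51.6% against 8.07% and Fam122a 47.9% against 6.87%. The sites called lower in muscle were positions 909 and 911 of mt-Rnr1, the mitochondrial 12S ribosomal RNA, and sites in Oaz1 and Tacc1. In heart 168 sites were called higher and 3 lower, with a median difference of 5.06 points (4.27 to 5.63). Aldh4a1, a mitochondrial enzyme of proline breakdown, reached 71.4% in heart against a mean of 21.5% elsewhere, Afg3l1 60.8% against 18.96%, Nomo1 54.9% against 14.1%, Entpd5 52.0% against 12.5% and Gpr137 56.6% against 19.99%. The sites lower in heart were Lars2, the mitochondrial leucyl-tRNA synthetase, at 59.8% against 87.8%, mt-Rnr1 909 at 3.38% against 17.1%, and Trio at 52.7% against 63.1%.

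Since each contrast is taken against the mean of the other 5, high levels in heart and muscle place the remaining tissues below it, and the lower calls there are not a separate result. There were 6 sites higher and 108 lower in lung and 14 higher and 103 lower in spleen. In lung, Wac fell to 24.4% against 53.4% elsewhere and Hdgf to 4.08% against 29.6%, and Prkrir had 0 of 21 unconverted reads, for which the 95% interval reaches 15.5%. In spleen, Rptor, a subunit of the mTORC1 kinase complex, was at 8.09% against 42.0%, and Ccdc107 at 4.07% against 47.2%. Both had higher levels at mt-Rnr1 909, 30.9% in lung and 30.5% in spleen, as had small intestine with 19.8%. Heart had 3.38% there, liver 2.23% and muscle 1.91%. The columns of heart, liver and muscle hold female libraries alone and the others a female and a male library each, so tissue and sex cannot be told apart here. These are shares of unconverted reads, and which modification lay at 909 was not tested. In small intestine 13 sites were higher and 73 lower. On sites the authors called in another tissue, an alternative chosen after the data were seen, 5 were higher in small intestine and 7 in spleen; with the 4 tissues of 2 or more libraries small intestine had 20 higher and 44 lower, and spleen 68 lower. Without lung and spleen small intestine had 35 higher and 263 lower. The higher ones of the 13 included Tbcc at 46890946, which the authors called in no tissue, 36.1% against 15.9%. Lung had 0% of 45 reads there and spleen 0% of 46, which lowers that mean. Other sites higher in small intestine were in the non-coding RNA Snhg20, 20.2% against 2.77%, and Caprin1 at 103771774, 19.7% against 2.67%. Neighbours within 10 nt were called higher as well, Tbcc at 46890936 with 34.9% and Caprin1 at 103771773 with 18.5%. Local failure of conversion at such neighbours is taken up below. The lower ones included Aldh4a1 at 5.04%, Aes at 5.51% and Gpd2, the mitochondrial glycerol phosphate dehydrogenase, at 5.86% against 26.5%. Lung and spleen had no coverage at 5 of 5 mitochondrial mRNA sites that the other 4 tissues covered by 1000 reads or more, and both had lower summed coverage.

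Liver was below the mean of the other tissues at 503 of 802 sites and above it at 297, with a median difference of -1.19 points (-1.51 to -0.879). At differences of 10 points or more, however, 37 sites were called higher and 15 lower. Ccdc107 reached 64.7% in liver against a mean of 35.04% elsewhere, Ppm1m 51.0% against 24.4%, Oaz1, which limits polyamine synthesis, 34.4% against 11.7%, Ptdss1 40.3% against 19.5% and Lrrc45 37.7% against 17.3%. Dmpk, a kinase of striated muscle, had 5.96% against 24.5%, Pde4dip 2.19% against 16.5% and Akt2 8.87% against 21.9%. The balance of calls in liver turned with the settings: with no minimum difference 93 of the same sites were higher and 357 lower. Without lung and spleen, an alternative chosen after the data were seen that also widened the test to 1227 sites, 38 were higher and 101 lower.

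**Figure D2:**
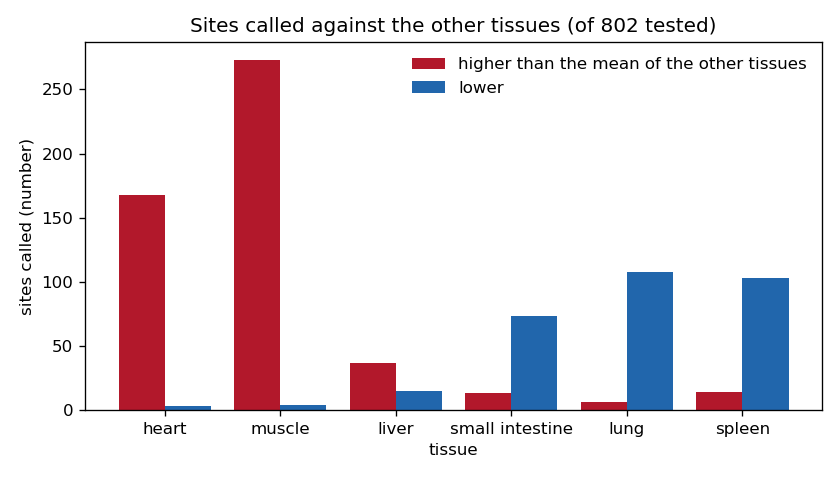
Number of sites (vertical axis) called higher (red) or lower (blue) in each tissue (horizontal axis) than the mean of the other tissues, of 802 tested by Fisher's exact test. Muscle had 273 higher and 4 lower, and lung 6 higher and 108 lower.

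Pairs of tissues kept sites whose transcripts were covered in only some tissues. Muscle was higher than lung at 463 sites and lower at 19 of 1097, higher than spleen at 399 and lower at 19 of 937, and higher than small intestine at 523 and lower at 39 of 1397. Median differences were 9.60 points (8.65 to 10.2) from lung, 9.91 (8.82 to 10.5) from spleen and 7.49 (6.55 to 8.25) from small intestine. Got2, the mitochondrial aspartate aminotransferase, had 58.8% in muscle (56.2 to 61.3) and 4.35% in lung (0.772 to 20.99, 23 reads; Fisher's exact adjusted p = 2.6e-07). Serinc2 had 76.0% in muscle and 18.8% in small intestine (Fisher's exact adjusted p = 2.7e-36). Rnf157 had 75.2% in muscle and 6.90% in spleen, and the site of the ribosomal protein gene Rpl3 had 80.6% of 36 reads in muscle and 0 of 20 in spleen, where the 95% interval reaches 16.1%. In the other direction, Tm9sf3 at 41214819 had 34.0% in small intestine and 5.13% in muscle (Fisher's exact adjusted p = 1.3e-14). Another listed site lies next to it at 41214820, so the limit given below for neighbouring sites applies. Cidea, a lipid droplet protein, had 25% of 44 reads in lung and 3.85% of 52 in muscle.

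Small intestine, lung and spleen differed from each other at few sites. Lung and spleen differed at 11 of 889, 8 of them higher in lung, with a median difference of 0. Ccdc107 had 21.6% in lung and 4.07% in spleen, and Atp2a2, the calcium pump of the sarcoplasmic reticulum, 13.6% and 0%. Higher in spleen were Sh3pxd2a, Igfbp6 at 40.1% against 26.99% and Ybx3, an RNA-binding protein, at 25.7% against 15.1%. Small intestine was higher than lung at 41 sites and lower at 12 of 1055, and higher than spleen at 32 and lower at 9 of 951. Tbcc at 46890936, within 10 nt of the other Tbcc site, was also called by the authors in no tissue. It had 34.9% of 518 reads in small intestine and no unconverted read among 49 in lung or 62 in spleen. Wac had 52.8% in small intestine and 24.4% in lung (Fisher's exact adjusted p = 1.4e-09). With medians of 65 and 56 reads per site in lung and spleen, differences of about 10 points were often not detectable.

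Heart and muscle, both striated muscle, were compared with a single heart library behind the heart column. Heart was higher at 88 sites and lower at 165 of 1645, with a median difference of -0.313 points (-0.855 to 0). Higher in heart were Adra1b, an adrenergic receptor, with 36.1% against 0 of 21 reads, Adcy5, an adenylyl cyclase of the heart, with 36.6% against 6.72% (Fisher's exact adjusted p = 5.7e-12), and Gid4 with 61.8% against 18.2%. Higher in muscle were Fam57b with 55.5% against 5.02%, Zfp652 with 42.7% against 11.8%, Dpp8 with 43.7% against 13.4%, Atn1 and Amotl1. On the 505 sites that the authors called in a further tissue, an alternative chosen after the data were seen, 35 sites were higher in heart and 36 lower.

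**Figure D3:**
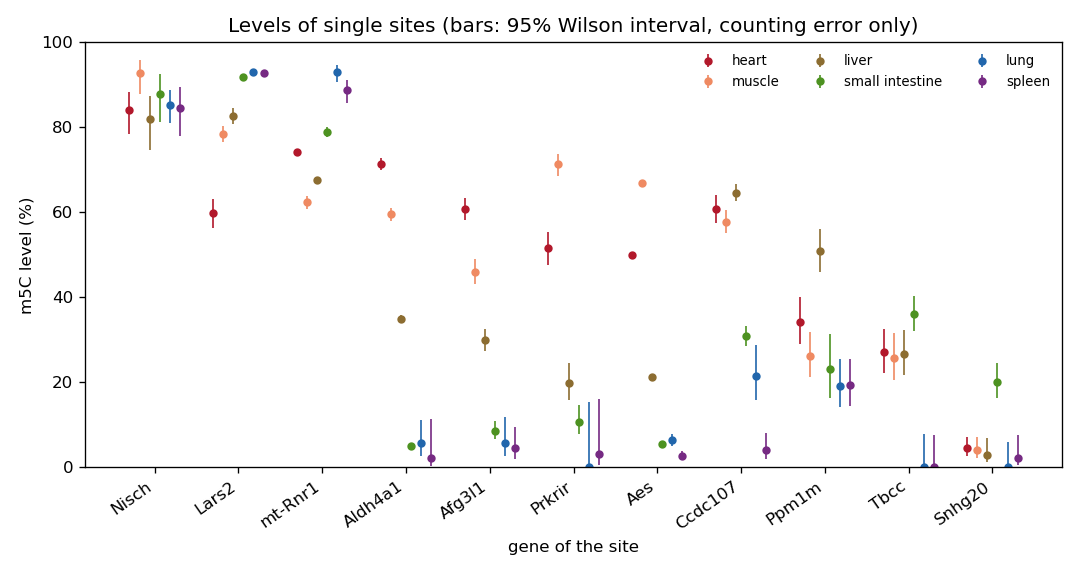
m5C level (vertical axis, percent) of single sites (horizontal axis, by gene) in the 6 tissues, with 95% Wilson intervals for counting error as bars. Nisch is above 80% in all tissues, while Aldh4a1 spans 2.174% in spleen to 71.4% in heart.

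Genes of oxidative phosphorylation and the TCA cycle had 17 tested sites in 15 genes. In heart 9 of them were called higher than in the other tissues and none lower, the same counts as when adjusted over the list alone, and the median difference of 11.1 points lay at percentile 99.8 of matched random lists. In muscle 5 were higher and none lower, at percentile 60.6. In liver none of the 17 was called, with a median of -3.96 points at percentile 0.145, and in small intestine 2 were lower, at percentile 1.21, which became 4.51 with a coverage minimum of 10. In spleen 3 were lower and in lung 1. Of all listed sites of these genes with at least 20 reads, 22 of 28 reached 10% in heart, 16 of 24 in muscle and 7 of 24 in liver. Some may thus be listed through heart. The random lists were matched on mean level alone, and no list was tested on sites called in another tissue. Slc25a4, the ADP/ATP carrier of heart and muscle mitochondria, had 48.6% in heart, 27.7% in muscle and 15.8% in liver. Cox7c at 86046657 had 20.3%, 19.1% and 11.5% in the same tissues, Atp5b at 128089039 12.7%, 4.08% and 2.42%, and Idh3b at 130283941 11.7%, 10.8% and 2.30%.

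Ribosomal proteins and translation factors had 10 tested sites, of which 5 were higher in heart, 3 higher in muscle and 2 lower in lung; the counts adjusted over the list alone were equal. Rpl23 at 97781822 had 34.1% in heart, 26.8% in muscle, 19.6% in liver, 9.88% in small intestine, 9.66% in spleen and 7.70% in lung. The heart median lay at percentile 98.6, but at percentile 81.7 with a coverage minimum of 10. Extracellular matrix genes had 9 tested sites with small differences: 1 was higher in heart, 1 higher in muscle and 1 lower in liver, also when adjusted over the list alone. Their medians lay at percentile 1.80 in heart, 97.8 in lung and 99.2 in spleen, and the heart and lung medians came inside the central 95% at a coverage minimum of 10, at 3.02 and 95.6. Col1a1, a collagen chain, had 14.6% in muscle, 10.8% in heart, 9.98% in lung and 9.60% in spleen. Lysosome and membrane transport genes had 8 tested sites, 3 higher in heart and 3 higher in muscle. Lower sites numbered 1 in lung, 1 in small intestine and 2 in spleen. Among the higher ones was Gaa, the lysosomal glucosidase, with 31.1% in muscle, 29.6% in heart and 3.82% in small intestine. In every list the counts over all sites equalled those adjusted over the list alone. Of 42 combinations of a list with a tissue, 10 lay outside the central 95% of matched random lists.

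The remaining lists had few sites covered everywhere. Striated muscle genes had 4 tested sites in 3 genes, with 1 higher in heart, 1 higher in muscle, 2 lower in small intestine, 1 lower in lung, and 1 higher and 2 lower in spleen. Their medians lay at percentile 1.32 in liver and 99.4 in lung. Glycolysis had 3, with Gpd1l, called by the authors in no tissue, at 12.1% in muscle and 1.91% in heart and the heart median at percentile 1.31, or 8.51 at a coverage minimum of 10. There were also secretory pathway genes with 3 tested sites, among them Sec61a1, a subunit of the translocon, at 38.3% in liver and 24.4% in heart. Immune genes had 2, with Csf1r, a macrophage receptor, at 49.9% in muscle and 31.7% in spleen, and Lyz1, a lysozyme of Paneth cells, at 11.6% in small intestine and 0.525% in heart. Both erythroid sites were higher in muscle, where Bpgm had 34.1% and Fech 15.3%. Endothelial genes had 2, with Vwf at 19.3% in heart and 10.1% in lung and none called. Of the lung epithelium list Abca3 was tested and not called, and of the smooth muscle list Des, which was higher in muscle and lower in lung, small intestine and spleen. Hepatocyte, intestinal epithelium and adipocyte genes had no site covered in all 6 tissues. Of the m5C machinery list, Nsun5, an rRNA methyltransferase, and the DNA methyltransferase gene Dnmt3a had 1 site each: Dnmt3a was called higher in muscle with 20.8% of 231 reads, and Nsun5 was called in no contrast.

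Sites were also counted by the number of tissues in which they reached 10%. Of the 802 sites, 35 did so in 6 tissues, 32 in 5, 34 in 4, 92 in 3, 205 in 2, 294 in 1 and 110 in none. Among all listed sites 969 reached 10% in 1 tissue alone, 375 of them in muscle, 314 in heart, 145 in liver, 91 in small intestine, 23 in lung and 21 in spleen. Of those 969, 294 (30.3%) were covered in all 6 tissues, so for the other 675 coverage was lacking somewhere. The highest mean levels belonged to Nisch at 86.1%, Lars2 at 83.1%, mt-Rnr1 911 at 77.5%, Znrf1 at 75.7% and Pabpc4, a poly(A)-binding protein, at 71.2%, followed by Trio, Trim41, Wac, Klhl26 and Sdc3. Nisch on chromosome 14 at 31186632 ranged from 81.9% in liver to 92.9% in muscle. Position 911 of mt-Rnr1, known to be methylated by Nsun4, had 93.0% in lung, 88.7% in spleen, 79.0% in small intestine, 74.3% in heart, 67.7% in liver and 62.4% in muscle. The authors called it in heart and small intestine alone, by a rule that is not given in the sources used here.

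**Figure D4:**
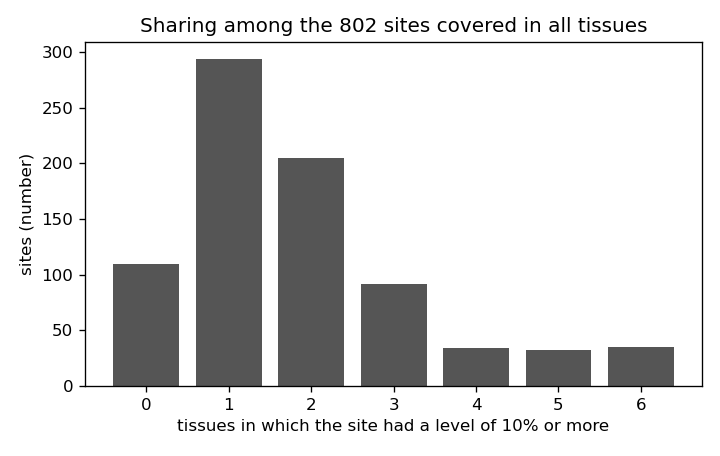
Number of sites (vertical axis) by the number of tissues in which the level was 10% or more (horizontal axis), for the 802 sites covered in all tissues. The largest class is 294 sites in 1 tissue, and 35 sites reached 10% in all 6.

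Of 1809 sites in protein-coding genes of 10 kb or more, 17.7% lay within 1 kb of the 5′ end of the gene, 16.7% within 1 kb of the 3′ end and 65.5% elsewhere. Sites near the 5′ end had higher levels than sites elsewhere in small intestine, with medians over genes of 7.62% and 3.29%, and in liver, with 9.97% and 5.26%. The permutation test over genes gave adjusted p = 6e-05 in small intestine, from the smallest p that 100000 resamples can give, and 9e-05 in liver. These were also the tissues where sites within 10 nt of another listed site had higher medians than isolated sites, as given below. The 5′ test was not repeated without those sites. The 5′ sites were also higher in spleen, 3.77% against 1.40% (permutation adjusted p = 0.00442), and in lung, 3.82% against 2.13% (permutation adjusted p = 0.024). Over single sites these were smaller and their ranges overlapped, 1.54% (0 to 4.55) against 1.01% (0.503 to 1.55) in spleen and 2.86% (1.79 to 3.70) against 1.92% (1.49 to 2.38) in lung. Heart and muscle gave 11.7% against 10.5% and 13.2% against 11.9%, with a permutation adjusted p of 0.104 in each. Tests of whether the 5′ difference itself differed between tissues, chosen after these values were seen, gave permutation adjusted p = 0.0924 for liver and for small intestine against heart, and 0.443 and 0.333 against muscle.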

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

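The tests of conversion, of column make-up and of muscle reads in lung were chosen after the results were seen; those on sites called in liver and on adjacent sites were fixed before their results were seen.

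Signals stood outside the comparisons of the report in 3 places. Eif2s3y, a Y-linked gene with a close X-linked relative, had 64 reads in the heart column, whose library is labelled female, with 65 in liver and 38 in muscle, whose libraries are labelled female as well. Columns that hold a male library had no more, 44 reads in small intestine, 11 in lung and none listed in spleen. There were 101 sites that the authors called in none of the 6 tissues although a tissue had 20 reads or more and a level of at least 10%. The lung column held 869 reads at 13 sites in 5 skeletal muscle genes that had no heart coverage.

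Levels were higher in heart and muscle than in lung, spleen and small intestine. Uniform failure of conversion in heart and muscle is argued against by the 5th percentile at sites with 100 reads or more. It was 1.79% in heart and 0.971% in muscle, below the smallest median excess of 5.86 points. This percentile cannot address failure of conversion that varies between sites, which stays open. Listing of sites because they were called in heart or muscle is argued against as the whole cause by sites the authors called in liver, where the smallest of 6 median differences was still 5.85 points. Small intestine covers the mitochondrial mRNA sites, so it does not share that feature of the lung and spleen columns. No other feature of make-up was checked, so a different make-up of the small intestine column stays open too. Over all 1397 sites covered in both, small intestine lay 7.49 points below muscle. At the 13 mitochondrial sites compared below, it lay above muscle instead. For lung and spleen a different make-up cannot be told apart from the tissue, since both lack all 5 mitochondrial mRNA sites that the other tissues covered deeply. The heart, liver and muscle columns hold female libraries alone, while small intestine, lung and spleen each hold a female and a male library. Tissue thus cannot be told apart from sex in this split, nor from the kit, which is not given per library. A biological difference between tissues stays open as a hypothesis, untested across animals.

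Sites within 10 nt of another listed site had higher medians than isolated sites in liver, 10.6% (8.37 to 12.5) against 5.61% (4.97 to 6.17), and in small intestine, 8.18% (6.04 to 10.3) against 3.57% (3.17 to 3.90). The other tissues did not share this: heart had 10.6% and 11.1%, muscle 7.47% and 12.1%, lung 0% (0 to 1.37) and 2.03% (1.78 to 2.44), and spleen 0% (0 to 0.971) and 1.40% (1.03 to 1.71). Local failure of conversion predicts that neighbours go together, and the Spearman correlation over pairs 1 nt apart was 0.659 over 53 pairs in liver and 0.672 over 50 pairs in small intestine, above the upper end of the central 95% of re-paired sites, 0.276 and 0.272. The correlation is across sites, which are not independent replicates, and it was also 0.911 in heart and 0.715 in lung, where clustered sites were not higher. Local failure of conversion may thus contribute, and methylation of neighbouring cytosines was not tested.

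Skeletal muscle transcripts in the lung column included Actn3 with 95 reads, Myh1 with 188, Myh4 with 255 and Ryr1 sites with up to 64. At these sites the lung column had 107 unconverted reads, 0.813 times the number expected at muscle levels (0.667 to 0.983, counting error), against 0.421 at the 802 common sites, or 0.146 there as the ratio of medians. Ryr1 had 9 of the 13 sites, and without it the ratio was 0.863 (0.654 to 1.12), but this rested on Actn3: without Actn3 it was 0.677 (0.522 to 0.863), and without both 0.492 (0.275 to 0.811), near that of common sites. A constant carry-over of muscle reads is argued against by the ratio of lung to muscle coverage, which differed 72.9-fold between Myh1, 13.7 lung reads per 1000 muscle reads, and Myh4, 0.188. Skeletal muscle of another fibre make-up in the lung samples, or low expression in lung, stays open and was not tested.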

How the results depend on the processing

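The tests on sites called by the authors in another tissue, without lung and spleen, with the authors' own calls and with the asymptotic chi-square were chosen after the data were seen; the others were fixed beforehand. Of 179 alternative values, 109 stayed within 1.5 times a count, inside an interval or on the same side of a range, 61 moved further and 9 list percentiles came inside the central range. This tally leaves out the separate counts of higher and lower sites, many of which moved too: without lung and spleen the lower sites rose from 3 to 15 in heart and from 4 to 15 in muscle. The balance of calls in liver turned, from 71.2% higher to 20.7% with no minimum difference and 27.3% without lung and spleen, where the sites tested also rose from 802 to 1227. The cause was not tested except where an alternative changes how many sites can pass. No paired analysis was possible because the columns are per tissue and carry no replicate number. Leaving out libraries, a replicate block, edgeR, limma and quasi-binomial models, agreement of replicates and female against male were not run because each tissue has 1 pooled column set. Alternatives on sequence context and context classes were not run without a genome sequence. With no minimum difference, sites called against the other tissues rose to 408 in heart, 450 in liver, 474 in lung, 530 in muscle, 553 in small intestine and 430 in spleen; at 20 points they were 38, 6, 22, 84, 7 and 16. For pairs, no minimum gave 119 for small intestine and lung, 25 for lung and spleen, 93 for small intestine and spleen and 628 for heart and muscle. At 20 points the pairs gave 170 for muscle and lung, 190 for muscle and small intestine, 154 for muscle and spleen, 11 for small intestine and lung, 1 for lung and spleen, 15 for small intestine and spleen and 42 for heart and muscle. Both follow from the threshold. A coverage minimum of 50 left 57 called in small intestine against the others, 27 for small intestine and spleen, 106 sites called in lung, 78 in spleen and 181 sites called in 1 of 6 tissues. Without lung and spleen, 139 sites were called in liver, 101 of them lower, and 298 in small intestine. On sites the authors called in a further tissue, fewer sites were tested: 353 were called for muscle and small intestine, 273 for muscle and spleen, 19 for small intestine and spleen and 71 for heart and muscle. The share higher in heart was then 49.3%, against 34.8%. A level of 5% gave 872 sites called in liver, 341 in lung, 697 in small intestine and 229 in spleen, with 87 called in 1 tissue and 93 in 6; a level of 20% gave 371 in heart, 204 in liver, 50 in lung, 399 in muscle, 152 in small intestine and 42 in spleen, with 96 and 15. Means in place of medians gave 13.9% in heart, 8.52% in liver, 4.30% in lung, 15.4% in muscle, 5.62% in small intestine and 4.20% in spleen; summed reads gave 21.7%, 9.28%, 6.90%, 19.5%, 5.75% and 7.62%, which put heart above muscle, and spleen and lung above small intestine. With 1 site per gene, 15.3% of sites lay near the 5′ end. For the lists, oxidative phosphorylation in small intestine moved to percentile 4.51 at a coverage minimum of 10. Ribosomal proteins in heart moved to 97.0 unmatched and 81.7 at a minimum of 10. Extracellular matrix moved in heart to 4.83 unmatched and 3.02 at a minimum of 10, and in lung from 97.8 to 96.5 with all sites, 93.8 unmatched and 95.6 at a minimum of 10. Glycolysis in heart moved from 1.31 to 8.51 at a minimum of 10. Depth limits lung and spleen most, with medians of 65 and 56 reads per site.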

Other observations

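The mitochondrial comparison below and its tests were chosen after the values were seen.

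There were 13 mitochondrial sites with at least 20 reads in heart, liver, muscle and small intestine. Among these tissues, all 13 had the highest level in small intestine. Small intestine is also the only one of these tissues with a male library, so tissue and sex cannot be told apart. Lung and spleen were higher at mt-Rnr1 911, with 93.0% and 88.7% against 79.0%, and at mt-Rnr1 909, with 30.9% and 30.5% against 19.8%. The authors called all 13 in small intestine and 7 of them there alone, so these 7 were listed through the tissue that was high. On the 6 sites that they also called in heart, liver or muscle, all 6 were highest in small intestine among the tissues compared. Of 18 comparisons at these 6 sites, 14 were called higher in small intestine by Fisher's exact test and none lower, and 3 sites were called higher than all 3 tissues. The mt-Cytb site at 14920, in the cytochrome b mRNA, had 75.1% in small intestine, 67.7% in muscle, 58.3% in heart and 46.3% in liver. The mt-Nd5 site at 12352 had 69.6%, 54.8%, 48.3% and 50.9% in the same order, and the mt-Nd4 site at 11069 32.4%, 16.5%, 17.7% and 12.7%. These are 6 sites of 1 small genome in 1 column per tissue, the mt-Cytb sites at 14917 and 14920 are neighbours, and a part of the listing through small intestine remains. Local failure of conversion was not tested at them.

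Transcripts covered in 1 tissue or few tissues carried sites too. In liver, Alb had 15.6% of 1177520 reads, Serpina3k, a serine protease inhibitor, 31.5% of 57789, Plg, the precursor of plasmin, 11.5% of 56566 and Ces1c 13.9% of 53551; hepatocyte genes had 8 sites covered in liver, 7 of them at 10% or more. In small intestine, Defa24, a defensin of Paneth cells, had 22.1% of 3324 reads. Tff3, a goblet cell peptide, had 6.28% of 28322 reads beside 20.5% of 492 in liver. Of 6 sites of intestinal epithelium genes, 5 reached 10%. Among all sites covered by at least 20 reads, 36.5% reached 10% in liver and 24.2% in small intestine. A site covered in few tissues may be listed because its level was high there, so these shares may follow from the listing. The only adipocyte gene with a site was Cidea. In spleen, Ms4a1, the B cell antigen CD20, had 12.7% of 63 reads. In muscle, Actn3 had 37.4% of 187291 reads while Myh4 had 1.27%. There were 282 sites in 245 genes with no value listed in any of the 6 tissues.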
